A study of Mus musculus with 2 samples.

How the data were processed

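RNA from mouse lymphocytes polarized in culture was compared on 2 two-colour microarrays, each hybridised with RNA of 1 polarized population and RNA of Th0 cells. Per the labels, the cells came from a TRP-1 mouse, and RNA of the Th1 or the Th17 population was labelled with Cy5 while RNA of the Th0 population was labelled with Cy3. RNA was purified on columns, and 500 ng of total RNA was amplified and labelled through an amino allyl step, per the labels' protocols. There was 1 array per comparison, with no replicate and no dye swap, and whether both arrays received the same Th0 RNA was not given in the sources used here.

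The deposited table held 1 value per probe and array for 36547 probes, with none missing, and its values were taken to be log2 ratios of the 2 channels as the authors processed them. The unit was settled from the values themselves. The most repeated value was −0.8485 on the Th1 and Th0 array, where 110 probes held it, and −0.4263 on the Th17 and Th0 array, where 162 probes held it. The other repeated values lay away from these by log2 of small whole-number ratios such as 2, 3/2 and 4/3, the pattern left by ratios of whole-number signals to which 1 constant per array had been added. On that reading, a probe with equal signals in both channels holds the most repeated value of its array, on the negative side. The scanner software, the background correction and the normalisation were not given in the sources used here. The median over probes was −0.11 on the Th1 and Th0 array and −0.05 on the Th17 and Th0 array, so neither array was centred exactly on 0, and how the constants were set stays unknown.

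The direction of the deposited ratio is also unsettled. The titles and the dyes name the polarized population over Th0, and the design fixed before the data were examined read the ratio that way and called it likely. The table itself states no numerator, and the cytokine genes that define each lineage lay on the side opposite to that reading. Signed values are therefore printed as deposited, as the negative or positive side of the ratio, and both readings are stated. The sizes and the counts per side do not depend on the choice. The difference between the 2 arrays does rest on both columns having the same order and on both arrays holding the same Th0 RNA, which the labels do not state.

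Probe annotation was matched to a current list of mouse genes (assembly GRCm38.p6, used for names alone) through gene numbers. Of the probes, 26926 carried 1 gene, 203 carried several genes and 9418 were unnamed here. Gene numbers matched for 26774 of the one-gene probes, 152 were not matched and kept the platform's symbol, and 0 symbols changed. The platform annotation can be old. Probes with several genes or none were left out of gene counts. The remaining probes were averaged per gene on the log2 scale, which gave 17501 genes, 11615 of them with 1 probe. No coordinates are given, because no genome build was named in the sources used here. No value column was left unused.

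Since each group held 1 array, no p-value was computed. Genes were counted when the absolute log2 ratio was at least 1, which is a 2-fold difference. Th17 was set against Th1 as the difference of the log2 ratios of the 2 arrays, which removes a dye effect shared by both. For 23 gene lists written before the data were examined, the median log2 ratio was placed among the medians of 10000 random lists of the same size. These were drawn from all named genes, since the table gives no expression level to match on. A percentile of 0 or 100 means that no random list, or every one, had a lower median. It describes these arrays and not the conditions. The lists covered the Th1, Th2 and Th17 programmes, regulatory T cell genes, TGF-beta responsive genes, cytotoxic effectors, interferon-stimulated genes, the cell cycle, naive and memory T cells, and activation and inhibitory receptors. They also covered glycolysis, cholesterol synthesis, STAT and cytokine feedback, apoptosis, chemokine receptors and homing, pan T cell genes, B cell markers, myeloid markers, class II antigen presentation, CD8 T cell and NK cell markers, red cell markers, stress and heat shock, and widely expressed control genes.

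Genes were named by a rule fixed beforehand. It took the 10 highest and 10 lowest genes on each array and in the difference, leaving out clone and model names and genes whose probes differed in sign. It added a panel of lineage genes, of which 17 are reported here, and of each list up to 4 members with the largest absolute value. Each of the 10 highest and 10 lowest genes had 1 probe, so their values rest on that probe alone. The panel genes also had 1 probe each, except Ccr6 and Foxp3 with 2. The spread between different probes of a gene, the sole repeat measurement, had a pooled SD of 0.52 on the Th1 and Th0 array and 0.50 on the Th17 and Th0 array over 5871 genes with 2 to 19 probes. It covers probe differences and not differences between samples. Probes whose weaker channel held at most 5 units were sought by testing whether the ratio, with the array's constant removed, was a ratio of whole numbers within 0.0001 log2 units. A match gives the smallest units that could yield the ratio, so a brighter probe with the same ratio matches too. There were 1086 such probes (2.97%) on the Th1 and Th0 array and 798 (2.18%) on the Th17 and Th0 array. The same search at shifted constants gave a mean of 0.259% and 0.230%. The search could miss very negative values, and some positive ones. Olfr820 on the Th1 and Th0 array had a ratio of stronger to weaker channel of 40.987, and Vip on the Th17 and Th0 array one of 44.008. Apoe, on the positive side of the Th1 and Th0 array, had one of 20.998. These lie near whole numbers but outside the tolerance, so counts among the genes furthest from 0 may be too low.

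The steps were tested on simulated data. Among 50 random lists with no shift on each array, 0% on the Th1 and Th0 array and 8% on the Th17 and Th0 array lay outside percentiles 2.5 to 97.5. A shift of 0.5 placed 100% outside on both. For 200 of 17501 simulated genes, the value was replaced by 1, 2 or 3 log2 units plus small symmetric noise. At 1 log2 unit, 60% passed the 2-fold threshold on the Th1 and Th0 array and 50% on the Th17 and Th0 array. At 2 or 3 log2 units, 100% passed on both. These shares follow from the settings, since 1 log2 unit is the threshold itself. They do not test the recovery of real changes. All simulated probes with at most 5 units were found, and 1.01% and 1.10% of simulated probes above 100 units were taken for them. The simulated log2 ratios were rounded within the tolerance, so this could not show the miss of very negative values.

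Alternatives fixed beforehand centred each array on its median, scaled each array to a common spread (the median absolute deviation, MAD), moved the threshold to 1.5-fold or 3-fold, took the median of probes, required every probe of a gene to pass, counted all probes, or kept genes with values on both arrays. Chosen after the data were seen were the removal of probes with at most 5 units and the centring on widely expressed control genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.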

Results

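The arrays compared gene expression in mouse lymphocytes that had been driven in culture towards the Th1 or the Th17 fate with that in Th0 cells, the usual name for cells cultured without a lineage-directing set of cytokines. Th1 cells are known for interferon gamma and Th17 cells for the interleukin 17 family. Lymphocytes came, per the labels, from a TRP-1 mouse, a strain whose T cells recognise a melanoma antigen, and the series concerns Th17-polarized cells in melanoma. There was 1 array for Th1 and Th0 and 1 for Th17 and Th0, and this number limits the precision: no value has a replicate and none was tested. Both arrays gave log2 ratios for 36547 probes, from which 17501 named genes were measured.

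**Figure D1:**
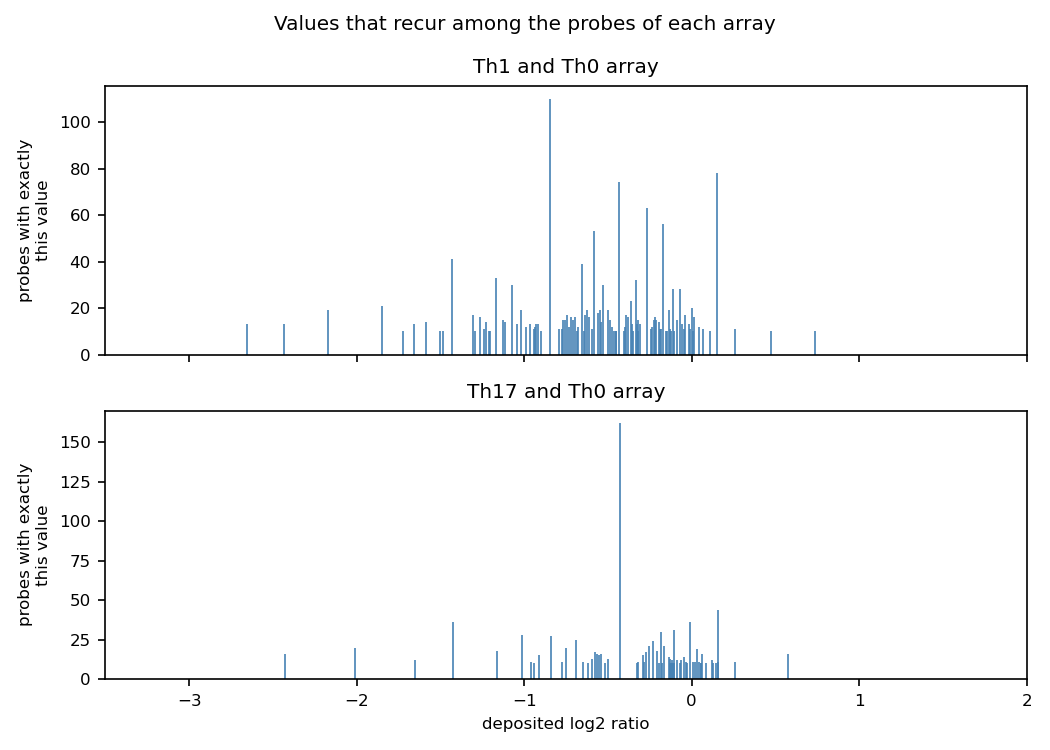
Values held by at least 10 of the 36547 probes of an array, with the deposited log2 ratio on the x axis and the number of probes that hold exactly that value on the y axis. The tallest lines stand at −0.8485 with 110 probes on the Th1 and Th0 array and at −0.4263 with 162 probes on the Th17 and Th0 array.

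The question of the Th1 and Th0 array was which genes differ between Th1-polarized and Th0 cells. Ifng, the gene of interferon gamma, lay at −2.02 (4.06-fold), and Tbx21, the master regulator of Th1 cells, at −1.25. The order of the ratio is unsettled: read as titled, a negative value means lower expression in the polarized cells, and with the sign turned it means higher expression there. The Th1 and Th0 values of Il10, an inhibitory cytokine, and of Csf2, a myeloid growth factor, were −2.35 and −2.97. On the opposite side lay the cytotoxic gene Prf1, which encodes perforin, at 3.43 (10.8-fold), and the eosinophil ribonuclease genes Ear3 at 3.88, Ear10 at 3.71 and Rnase2a at 3.73.

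Of the 17501 genes, 1784 were at least 2-fold apart on the Th1 and Th0 array. The negative side held 1211 of them (67.9%) and the positive side 573. Centring the array on its median moved the negative share to 56.5%, and centring it on control genes, which lowers each value by their median of 0.25, moved it to 86.6%.

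Interferon-stimulated genes leaned to the negative side of this array. Their median was −0.37 over 29 measured members, at percentile 0.28 of random lists, and 4 members lay at least 2-fold on the negative and 1 on the positive side. Here and below, members of a list called negative or positive are those at least 2-fold to that side. Gbp2, a guanylate-binding protein, lay at −1.49, Ifit3 at −1.45 and Usp18 at −1.33, while the transcription factor gene Irf8, used by myeloid cells too, lay at 2.34. The Th1 programme did not lean as a group, with 4 of 20 members at least 2-fold on each side, a median of −0.19 and percentile 16.0. Within it, the receptor gene Il18r1 and Ifng lay at −2.03 and −2.02. Havcr2, the gene of the inhibitory receptor Tim-3, lay at 2.69 and Eomes, a relative of Tbx21, at 2.29, although the 2 Eomes probes differed widely (SD 2.83). Cytotoxic effector genes lay on the positive side as a group. They had a median of 0.73 over 20 members, percentile 100, 9 positive and 2 negative members, and values of 2.61 for Gzmk, 2.59 for Serpinb6b and 2.51 for Gzmg beside Prf1. Centring on control genes moved the medians of interferon-stimulated, Th1 programme and cytotoxic effector genes to −0.63, −0.45 and 0.48. Granzymes C to G are closely related copies whose probes may share signal.

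Markers of myeloid cells had the most distant median of all lists on the Th1 and Th0 array, 1.82 over 16 members at percentile 100. Of these, 15 lay above 0, and 13 were at least 2-fold positive and 0 at least 2-fold negative. Fcer1g and Tyrobp, adaptor genes of myeloid receptors, lay at 2.98 and 2.52, the neutrophil gene S100a9 at 1.98 and the complement gene C1qb at 1.98. Class II antigen presentation genes lay on the same side, with a median of 0.42 over 10 members (percentile 99.7), 2 positive members, H2-Aa at 1.33 and Cd74 at 1.16. Pan T cell genes lay opposite, with all 11 members below 0, a median of −0.69 (percentile 0.10) and 3 members at least 2-fold apart. These were Cd3d at −1.43, Cd28 at −1.39 and Cd4 at −1.17. Naive and memory T cell genes had a median of −0.54 over 12 members (percentile 0.42), with Satb1 at −1.84, Il7r at −1.29 and Ccr7 at −1.20 on the negative and Myb at 1.01 on the positive side. The 2 probes of Myb differed widely (SD 2.15). B cell markers had a median of −0.14 over 10 members (percentile 33.8), with Cr2 at −1.12, and CD8 T cell and NK cell markers one of −0.44 over 9 (percentile 3.32), with Klrc1 at −2.49 and Klrb1c at 3.22. Red cell markers had a median of 0.18 over 5 members at percentile 87.0, which turned to −0.070 when the array was centred on control genes, and 0 members were 2-fold apart. That centring also moved the median of class II genes to 0.17.

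Several metabolic and growth-related groups lay slightly on the positive side of this array, as did the widely expressed control genes, whose median was 0.25 over 15 members (percentile 98.99). Glycolysis genes had a median of 0.43 over 15 members (percentile 99.96), with Tpi1 at 0.69, and 0 of them were 2-fold apart. Cholesterol synthesis genes had a median of 0.36 over 16 members (percentile 99.97), with Hmgcs1 at 1.61, Idi1 at 1.33 and Msmo1 at 1.09. Stress and heat shock genes had a median of 0.53 over 13 members (percentile 99.96), with the chaperone genes Hspa5 at 1.62 and Hspd1 at 1.25. Cell cycle genes had a median of 0.23 over 23 members (percentile 99.66), which turned to −0.027 when the array was centred on control genes. The same centring moved the medians of glycolysis genes to 0.18, of cholesterol synthesis genes to 0.11 and of stress and heat shock genes to 0.27. Of the cell cycle genes, Bub1 lay at 1.05 and Mki67, the gene of the Ki-67 proliferation antigen, at −1.51.

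The Th17 programme also leaned to the negative side of the Th1 and Th0 array, with a median of −0.67 over 17 members, percentile 0.02 and 4 negative members. Among these were Il22 at −2.53, Socs3 at −1.26 and Il21 at −1.23, and Il23r lay at −1.02. The genes of the interleukins that name the lineage, Il17a and Il17f, lay at 0.29 and 0.06, Ccl20 at −0.67 and Ccr6 at −0.07. The Th2 programme had a median of −0.23 over 14 members (percentile 14.4), with 2 negative members, Gata3 at −1.49 and Il24 at −1.27. Il4, Il5 and Il13, its cytokine genes, lay at 0.42, 0.04 and −0.67. Regulatory T cell genes had a median of 0.12 and a mean of −0.08 over 14 members (percentile 92.7). Foxp3, their master regulator, lay at 0.54, and Il10 was the 1 member past 2-fold. TGF-beta responsive genes had a median of 0.14 and a mean of −0.04 over 11 members (percentile 91.8), with Ski at −1.01. The medians of both groups turned negative when the array was centred on control genes.

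Activation and inhibitory receptor genes had a median of −0.27 over 16 members (percentile 7.98), and Csf2 was the 1 member past 2-fold. Chemokine receptors and homing genes had a median of −0.31 over 19 members (percentile 3.42), with Cxcr6 at −1.65 and Ccr7 at −1.20. STAT and cytokine feedback genes had a median of −0.16 over 14 members (percentile 28.1), with Socs3 at −1.26 and the kinase gene Pim2 at −1.23. Apoptosis regulators had a median of −0.02 over 12 members at percentile 66.5, and the median turned positive when the array was centred on its own median. Il12rb2, part of the interleukin 12 receptor, lay at −0.59 and Gzmb, the gene of granzyme B, at 0.47.

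The 10 highest genes on the Th1 and Th0 array began with Dixdc1 at 5.04 and also held the lipid carrier gene Apoe at 3.54, the desmosome gene Dsc2 at 3.39, the protease inhibitor gene Slpi at 3.37 and the mast cell and basophil protease gene Prss34 at 3.31. The 10 lowest were Olfr820 at −6.21, Prl5a1 at −6.08, Obox2 at −5.89, Olfr1290 at −5.85, Tpbpb at −5.32, Slc25a21 at −5.12, Vtcn1 at −5.12, Kbtbd12 at −5.10, Dkk2 at −4.98 and Cyp2j6 at −4.94. For 7 of these 10 a weaker channel of at most 5 units was found, so their sizes probably rest on very low signal, while among the 10 highest it was found for 0. The ratios of stronger to weaker channel of the rest, Olfr820 (40.987), Olfr1290 (32.009) and Dkk2 (17.503), lay near ratios of whole numbers, outside the search's tolerance. So did that of Apoe (20.998), among the 10 highest. These 4 genes may rest on such a channel too.

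The Th17 and Th0 array addressed which genes differ between Th17-polarized and Th0 cells. Il17a, which encodes the cytokine that names the lineage, lay at −5.37 (41.4-fold), Il22 at −5.79 (55.5-fold), Il21 at −4.17 (18.1-fold) and Il17f at −2.38 (5.20-fold). The chemokine gene Ccl20 lay at −6.48 (89.5-fold) and Il23r, part of the interleukin 23 receptor, at −1.88. On the opposite side lay genes of cytotoxic granules, with Gzmk at 4.50 (22.6-fold), Gzmg at 4.03 and Gzmb at 2.83 (7.13-fold). As titled, the Th17 cytokine genes would be lower and the granzyme genes higher in Th17 than in Th0 cells. With the sign turned, the reverse holds.

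On this array 1474 genes were at least 2-fold apart, 966 (65.5%) on the negative and 508 on the positive side. The Th17 programme had a median of −1.73 over 17 measured members at percentile 0, with 10 negative members and 1 positive member. The positive one was Nfkbiz at 1.19, which was named after its value was seen. Ccr6, the receptor for Ccl20, lay at −0.76.

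TGF-beta responsive genes lay on the side of the Th17 cytokines, with a median of −0.56 over 11 members, percentile 0.21 and 5 negative members. Itgae, the integrin chain CD103, lay at −2.19, Tgfbi at −2.02, Ldlrad4 at −1.80 and Pmepa1 at −1.58. Regulatory T cell genes had a median of −0.38 over 14 members (percentile 0.72), with 4 negative members and 1 positive member. Nt5e, the ectoenzyme CD73, lay at −2.36 and Ctla4 at −1.06, while Entpd1, the ectoenzyme CD39, lay at 1.47, and Foxp3 at 0.44 and Il10 at −0.36 did not pass 2-fold. The Th2 programme had a median of −0.22 over 14 members (percentile 6.91) with members on both sides: Il9 lay at −4.33 and Il24 at −1.56, and Nfil3 at 1.62, Il5 at 1.5 and Gata3 at 1.28. Il4 and Il13 lay at −0.29 and 0.36.

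Cytotoxic effector genes were furthest on the positive side, with a median of 2.44 over 20 members at percentile 100, 13 positive and 0 negative members. Serpinb6b lay at 4.08 and Serpinb9, an inhibitor of granzyme B, at 3.83, but the ratio of Serpinb6b matched a weaker channel of 5 units. The Th1 programme lay on the same side, with a median of 0.90 over 20 members (percentile 100) and 9 positive members against 1 negative member (Lta at −1.82, named after its value was seen). Havcr2 lay at 3.23, Nkg7 at 2.39, Eomes at 2.33 (SD 2.34 over 2 probes) and Txk at 2.22, and the panel genes Il12rb2, Tbx21 and Ifng at 1.01, 0.87 and −0.83. Interferon-stimulated genes had a median of 0.07 over 29 members (percentile 91.0), with 3 positive members, among them Irf8 at 2.30, Isg20 at 1.63 and Mx1 at 1.01. Cholesterol synthesis genes had a median of 0.56 over 16 members (percentile 100), with 4 positive members, Hmgcs1 at 2.64, Msmo1 at 1.78, Idi1 at 1.56 and Cyp51 at 1.37.

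T cell genes lay on the negative side of the Th17 and Th0 array. Pan T cell genes had a median of −1.0 over 11 members at percentile 0, with 5 negative members and values of −1.34 for Cd5, −1.27 for Cd4, −1.26 for Cd2 and −1.23 for Lat. Naive and memory T cell genes had a median of −0.77 over 12 members (percentile 0), with 4 negative members, among them the homing receptor genes Ccr7 at −2.25 and S1pr1 at −1.27, and Bach2 at −1.29. Activation and inhibitory receptor genes had a median of −0.37 over 16 members (percentile 0.51), with 6 negative members and 1 positive member. Il2, the T cell growth factor gene, lay at −2.50, Btla at −1.36 and Nr4a1 at −1.09, while Tnfrsf9 lay at 1.10, with 2 probes that differed widely (SD 2.26). Chemokine receptors and homing genes had a median of −0.44 over 19 members (percentile 0.02), with 5 negative and 2 positive members, of which Ccr2 lay at 2.16 and Cxcr3, named after its value was seen, at 1.34. Cxcr4 lay at −1.49.

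Cell cycle genes had a median of −0.33 over 23 members (percentile 0.45) and 0 were 2-fold apart, with Cdk1 and Mki67 both at −0.83. STAT and cytokine feedback genes had a median of −0.32 over 14 members (percentile 1.5), with Socs3 at −1.54, Socs2 at −1.37 and Il2rb at 1.65. Glycolysis genes had a median of −0.07 over 15 members (percentile 39.6) and apoptosis regulators one of −0.07 over 12 (percentile 39.2), with the death receptor gene Fas at −1.63. Stress and heat shock genes had a median of 0.15 over 13 members (percentile 94.1), with Hspa5 at 1.19 and Hmox1 at −1.17. The control genes had a median of −0.02 and a mean of 0.05 over 15 members (percentile 51.8), and their median turned positive when the array was centred on its own median.

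Myeloid markers had a median of 0.50 over 16 members on the Th17 and Th0 array at percentile 100, with 6 positive members and 1 negative member. S100a9 lay at 2.14, C1qb at 2.01 and C1qc at 1.66, while Cd14, a monocyte receptor, lay at −2.04. Class II antigen presentation genes had a median of −0.25 over 10 members (percentile 7.45), with Cd86 at −1.93 and Cd83 at −1.10. B cell markers had a median of 0.07 and a mean of −0.09 over 10 members (percentile 78.0), with Cr2 at −1.25. CD8 T cell and NK cell markers had a median of −0.33 and a mean of 0.06 over 9 members (percentile 4.17), with Klrb1c at 3.72, Klrc1 at −2.17 and Klra3 at 1.15. Red cell markers had a median of 0.18 over 5 members (percentile 86.8), with 2 positive members, the globin genes Hbb-b1 at 1.51 and Hba-a1 at 1.26.

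The 10 highest genes of this array were led by Dsc2 at 5.79, the serine protease inhibitor gene Serpinb9b at 5.61 and Dixdc1 at 5.02, and also held Tmsb15a at 4.22, the chemokine gene Ccl2 at 4.06, Afp at 4.01 and H2-Q10 at 3.99. Beside Ccl20, Il22 and Il17a, the 10 lowest held the neuropeptide gene Vip at −5.89, Nsun7 at −5.78, Mmp1b at −5.38 and the olfactory receptor genes Olfr181 at −6.77, Olfr1233 at −6.21, Olfr1284 at −5.60 and Olfr944 at −5.51. A weaker channel of at most 5 units was found for 3 of these 10 lowest genes, Olfr1233, Nsun7 and Olfr1284. The ratios of stronger to weaker channel of Olfr181 (80.975), Vip (44.008), Olfr944 (33.996) and Mmp1b (30.994) lay near whole numbers, outside the search's tolerance. These genes may rest on such a channel too.

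**Figure D2:**
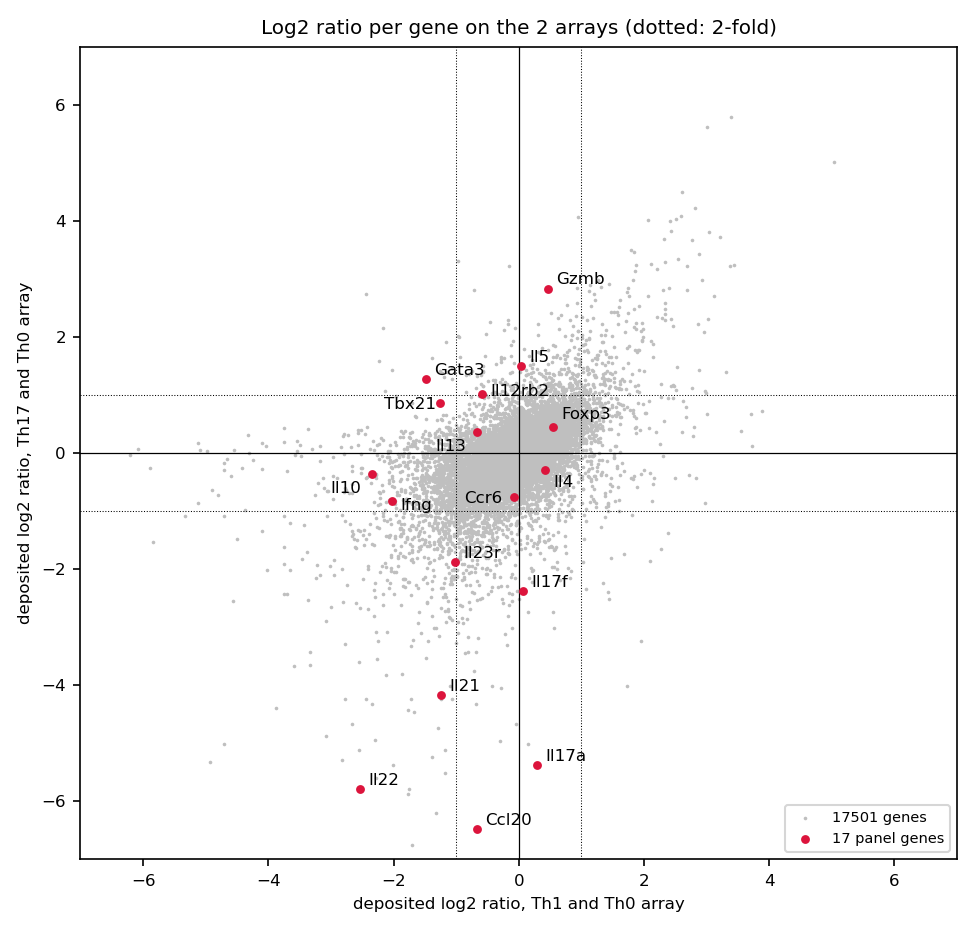
Each point is 1 of 17501 genes, with the deposited log2 ratio of the Th1 and Th0 array on the x axis and that of the Th17 and Th0 array on the y axis; the 17 panel genes are in red and dotted lines mark 2-fold. Il17a lies near 0 on the x axis (0.29) and at −5.37 on the y axis, whereas Ifng lies at −2.02 and −0.83.

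Th17 and Th1 cells were set against each other as the Th17 array's log2 ratio minus that of the Th1 array, on the assumption, not stated in the labels, that both arrays held the same Th0 RNA. The cytokine genes Il17a, Il22, Il21 and Il17f differed by −5.67 (50.8-fold), −3.26, −2.94 and −2.44, and Ccl20 by −5.82. The Th1 genes Tbx21, Il12rb2 and Ifng lay on the opposite side at 2.12, 1.60 and 1.19, as did Gata3 at 2.77. As titled, a negative difference means lower expression in Th17 than in Th1 cells, and with both signs turned it means higher expression there. In all 1425 genes were at least 2-fold apart, 632 (44.4%) on the negative and 793 on the positive side. Which side held more genes depended on the scaling, since the negative share was 51.1% with both arrays centred on their medians, 54.0% with both scaled to a common spread and 22.3% with both centred on control genes. The last adds 0.28 to each difference, which moves the median of a list and not its percentile.

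The Th17 programme had a median difference of −0.86 over 17 members at percentile 0, with 8 negative members and 1 positive member, and the Th1 programme one of 0.61 over 20 members at percentile 100, with 9 positive members and 1 negative member. The members at least 2-fold to the other side, Nfkbiz at 1.79 and the chemokine gene Ccl5 at −1.11, were named after their values were seen. Cxcr3, a chemokine receptor of Th1 cells, differed by 2.19, Fasl by 2.07 and Il18rap by 1.82. Il23r and Ccr6 differed by −0.86 and −0.68. Interferon-stimulated genes had a median difference of 0.37 over 29 members (percentile 100), with 9 positive and 0 negative members, led by Isg20 at 1.87, Usp18 at 1.61, Ifit1 at 1.56 and Ifit3 at 1.52. TGF-beta responsive genes lay on the side of Il17a, with a median of −0.48 over 11 members (percentile 0.11) and 4 negative members, led by Itgae at −2.84 and Tgfbi at −2.24. Cytotoxic effector genes lay on the side of Ifng, with a median of 1.37 over 20 members (percentile 100), 12 positive members, Gzmb at 2.36 and Gzmk at 1.89.

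Myeloid markers had a median difference of −1.15 over 16 members (percentile 0), with 8 negative members, among them Cd14 at −2.88, Itgax at −2.31, Ctss at −2.24 and Lyz2 at −2.23, although the 4 probes of Lyz2 differed widely (SD 2.11). Class II genes had one of −1.03 over 10 members (percentile 0), with 6 negative members, Cd86 at −1.57 and Cd74 at −1.30. Cell cycle genes had one of −0.70 over 23 members (percentile 0), with 6 negative members, Bub1b at −1.36 and Ccna2 at −1.31. The control genes themselves had a median difference of −0.20 over 15 members (percentile 2.89), with the tubulin gene Tuba1b at −1.12. Glycolysis genes had a median of −0.33 over 15 members (percentile 0.27), with Ldha at −0.83, and naive and memory T cell genes one of −0.28 over 12 (percentile 0.80), with Ccr7 at −1.05. The median of stress and heat shock genes was −0.28 over 13 members (percentile 1.13), with Hmox1 at −1.44, and that of chemokine receptors and homing genes −0.21 over 19 members (percentile 1.33), with Itgae at −2.84 and Ccr2 at 2.22. Both of these medians turned positive when the arrays were centred on control genes, and those of glycolysis and of naive and memory T cell genes moved to −0.055 and −0.0047, of cell cycle genes to −0.42 and of TGF-beta responsive genes to −0.20. On the positive side, the same centring moved the medians of interferon-stimulated genes to 0.65 and of cholesterol synthesis genes to 0.55.

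Cholesterol synthesis genes had a median difference of 0.27 over 16 members (percentile 98.3), with Hmgcs1 at 1.03. The Th2 programme had one of 0.15 over 14 members (percentile 82.3), which was 0.011 with both arrays scaled to a common spread and 0.43 with control-gene centring, with Il9 at −3.64 and Il5 at 1.46, while Il13 and Il4 differed by 1.03 and −0.71. Regulatory T cell genes had a median of −0.04 over 14 members (percentile 26.8), with Nt5e at −2.46 and Il10 at 1.99 and Foxp3 at −0.10. Activation and inhibitory receptor genes had one of −0.03 over 16 members (percentile 28.3), with Csf2 at 2.91 and Il2 at −1.91. STAT and cytokine feedback genes had a median of −0.13 and a mean of 0.01 over 14 members (percentile 8.77), with Socs2 at −1.84 and Pim2 at 1.80. The medians of these 3 groups, Foxp3 included, turned positive with control-gene centring. Apoptosis regulators had a median of 0.13 and a mean of −0.12 over 12 members (percentile 76.7), with Bcl2a1a at −1.83. Pan T cell genes had a median of 0.12 over 11 members (percentile 72.4), which turned to −0.016 when both arrays were scaled to a common spread, with Cd28 at 1.31. B cell markers had a median of 0.10 over 10 members (percentile 69.0), CD8 T cell and NK cell markers one of 0.32 over 9 (percentile 96.6) with Klra3 at 1.72, and red cell markers one of 0.39 over 5 (percentile 95.4) with Hbb-b1 at 1.33.

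Genes at the ends of the difference probably often rested on weak signal. The 10 lowest were Ccl20, Ngdn at −5.75, Il17a, Olfr938 at −5.19, Trim6 at −5.16, Olfr181 at −5.06, Olfr1233 at −4.89, Gdf6 at −4.67, Ocrl at −4.63 and Olfr944 at −4.34. For 5 of them a weaker channel of at most 5 units was found on 1 of the arrays or both. The 10 highest were Olfr820 at 6.18, Prl5a1 at 6.15, Obox2 at 5.64, Vtcn1 at 5.28, Kbtbd12 at 5.15, Dkk2 at 5.02, Stpg1 at 4.61, Akr1c6 at 4.56, Edil3 at 4.53 and Pramel4 at 4.41, and such a channel was found for 8 of them. Both counts may be too low. Olfr181 and Olfr944 on the Th17 and Th0 array, and Olfr820 and Dkk2 on the Th1 and Th0 array, lay near ratios of whole numbers but outside the search's tolerance.

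**Figure D3:**
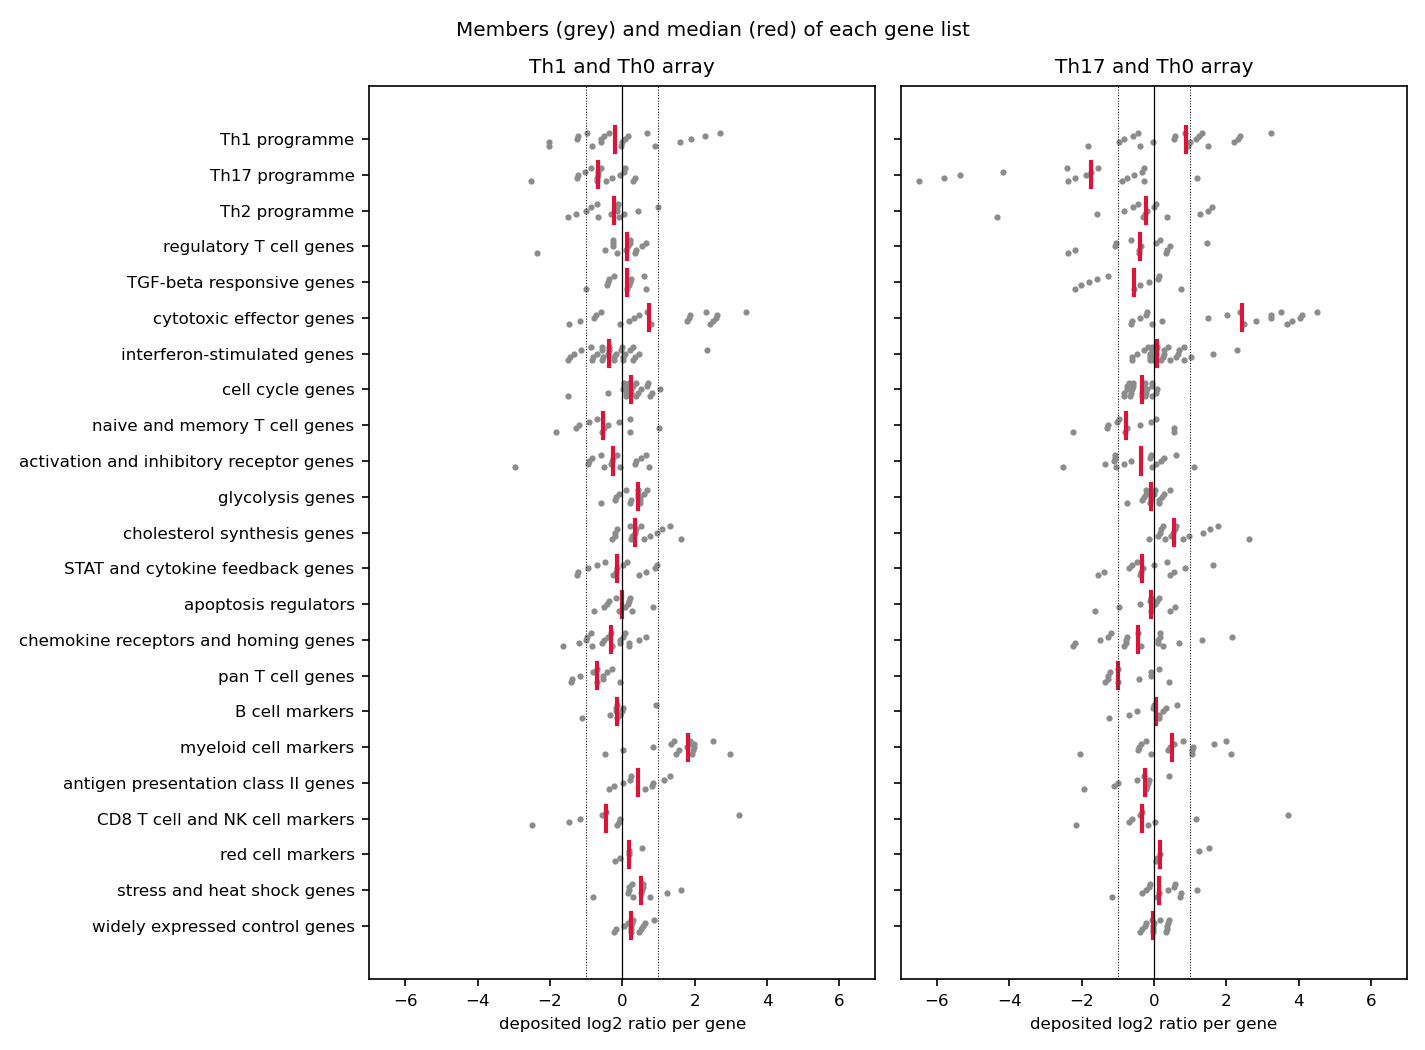
Deposited log2 ratio of each measured member (grey points) and the median (red line) of the 23 gene lists on the Th1 and Th0 array and on the Th17 and Th0 array, with dotted lines at 2-fold. The medians are 0.73 and 2.44 for cytotoxic effector genes, −0.67 and −1.73 for the Th17 programme and 1.82 and 0.50 for myeloid markers.

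Across the 17501 genes, which are not independent replicates, the log2 ratios of the 2 arrays correlated with a Pearson r of 0.53 and a Spearman rho of 0.54. Both arrays carried Th0 RNA in the same dye, and unchanged groups simulated as if it were 1 shared RNA gave an r of 0.50. That value follows from giving every RNA equal noise, whatever its size, and is not drawn from these data. The covariance was 0.233 against a simulated 0.131, a difference of 0.102. The simulated noise (SD 0.36 per RNA) was set from the spread between probes of a gene alone, so it leaves out variation between RNA samples, and the difference is no estimate of a shared effect. The share of genes with the same sign on both arrays was 69.4%, against 66.6% in the simulation, a share fixed by equal noise in the same way. The negative side of both arrays held 404 genes at least 2-fold apart, where independent lists would share 66.8, and the positive side of both held 221, where independent lists would share 16.6. Dixdc1, Dsc2, Klrb1c and Gzmk were among those positive on both, and Il22, Il21 and Ccr7 among those negative on both. Independent lists leave out any sharing of Th0 RNA. Whether it was shared is not stated, and it could not be split with 1 hybridisation per array, so part of the excess may come from it. There were 14 genes negative on the Th1 and positive on the Th17 array, and 18 with the opposite signs.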

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

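Chosen only after the results they measure had been seen were the tests of the ratio's order on both arrays, of exchanged titles, of a weaker channel of a few units in the Th17 genes and of a lower share of T cells. The Th17 cytokine genes lay on the negative side of the Th17 and Th0 array, against the order that its title names. An exchange of the titles is argued against by Il17a and Il17f, whose median size was 0.18 on the array titled Th1 and 3.88 on the array titled Th17. A weaker channel of at most 5 units was found for 0 of the 7 genes Il17a, Il17f, Il21, Il22, Il9, Ccl20 and Il23r. That leaves weak signal above that level open, and the search can miss very negative values. A candidate explanation, a hypothesis, is that the table gives Th0 over polarized RNA: genes that respond to TGF-beta, a textbook Th17-inducing cytokine, lay at percentile 0.21 on the Th17 array, and interferon-stimulated genes at 0.28 on the Th1 array, each on the side of that lineage's cytokine genes, where the titled order predicted the upper 2.5%. On the Th1 array the Th1 programme, at percentile 16.0 with 4 members at least 2-fold on each side, did not go that way. Nor did the cytotoxic effector genes, at percentile 100 on the positive side, so the order stays unsettled, most of all on that array.

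Myeloid markers lay on the positive side of the Th1 and Th0 array, with a median of 1.82. A lower share of T cells was taken to move other cell types alike, but the myeloid median exceeded the higher of the B cell and the CD8 T and NK cell medians by 1.96. This cannot exclude a lower share, because whether B cells or NK cells were present is not known. All 11 pan T cell genes lay below 0 on this array, with a median of −0.69 (percentile 0.10), as a lower share predicts. A shift of brightly expressed genes is argued against by ribosomal protein genes, whose upper 2.5% began at 0.70. Cells of the granulocyte and myeloid lineages in 1 of the 2 RNAs may account for the myeloid markers, as a hypothesis. On the Th1 and Th0 array, 14 basophil, mast cell and eosinophil markers not looked at before had a median of 1.83, at percentile 100. Of these, 11 lay at least 2-fold on the positive side and 1, Csf1 at −2.42, on the negative. On the Th17 and Th0 array their median was 1.40, also at percentile 100, with 7 at least 2-fold positive and 0 at least 2-fold negative. Among the granule genes in this set, Cpa3 lay at 1.82 and Prg2 at 2.07 on the Th1 and Th0 array, while Kit, Cd63, Hgf and Csf1 are also used by other cells. The labels name no sort or gate that would remove such cells, which RNA would hold them depends on the order of the ratio, and a difference in the lymphocytes themselves stays open as untested.

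Genes at least 2-fold apart were mostly on the negative side of both arrays. Without probes found to have a weaker channel of at most 5 units, the negative share was 65.0% on the Th1 and Th0 array and 62.8% on the Th17 and Th0 array. That argues against the probes found as the whole cause. The search could miss very negative values, and the share without any missed probes was not measured, so such probes are not excluded. Weak signal in general could not be told apart from a difference between the cells: olfactory receptor genes, which lymphocytes are not known to use, passed 2-fold on the negative side 2.32 and 1.40 times as often as the remaining genes, and the 1.5 times set beforehand was exceeded on 1 array alone. Of 899 olfactory receptor genes, 15.0% were negative on the Th1 and Th0 array against 6.48% of the remaining genes. At least 2-fold apart were 135 on the negative and 5 on the positive side of that array, and 68 and 4 on the Th17 and Th0 array. Their positive shares were 0.56% and 0.44%, against 3.42% and 3.04% of the remaining genes, so they leaned to the negative side on both arrays. No threshold was set beforehand for the positive side. The negative share also depends on each array's constant, which was not tested as a cause. Equal signals in the 2 channels would lie at −0.8485 on the Th1 and Th0 array and at −0.4263 on the Th17 and Th0 array. A 2-fold negative value thus needs a smaller ratio of signals than a positive one. On the Th1 and Th0 array, Tbx21 at −1.25 had a ratio of stronger to weaker channel of 1.32, and Bub1 at 1.05 one of 3.73. Weak signal with near-equal channels would therefore lean to the negative side. On that array the negative share was 56.5% with centring on the median, which by construction pulls the sides together, and 86.6% with centring on control genes. On the Th17 and Th0 array it was 62.0% and 63.6%.

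Some genes lay at least 2-fold on opposite sides of the 2 arrays, and these differences between the arrays were not tested. Gata3, the Th2 master regulator, lay at −1.49 on the Th1 and at 1.28 on the Th17 array, a difference of 2.77. Ngdn lay at 1.74 and −4.01, a difference of −5.75, and its ratio on the Th1 array matched a weaker channel of 1 unit. On the Th17 array its ratio of stronger to weaker channel (11.999) lay near a whole number, outside the search's tolerance. Olfr938 lay at 1.96 and −3.23, a difference of −5.19, with ratios that matched a weaker channel of 1 unit on both arrays. Such a match gives the smallest units possible, so the channels may have been brighter.

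Probes that carry no gene name here also held large values, in a part of the table that no gene comparison used. Extremes were taken among those for which no weaker channel of at most 5 units was found, a search that could miss very negative values. On the Th1 and Th0 array the highest such probe lay at 4.02 and the lowest at −6.63. On the Th17 and Th0 array they lay at 4.64 and −6.62. Of 9418 unnamed probes, 1398 (14.8%) on the Th1 and Th0 array and 995 (10.6%) on the Th17 and Th0 array were at least 2-fold apart.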

How the results depend on the processing

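The alternatives that leave out probes with at most 5 units and that centre on control genes were chosen after the data were seen; the others were fixed before the data were examined. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. The counts of genes at least 2-fold apart (1784 for Th1 against Th0, 1474 for Th17 against Th0 and 1425 for Th17 against Th1) moved by construction with the threshold, to 4545, 3656 and 3594 genes at 1.5-fold and to 608, 575 and 545 at 3-fold. Counting all probes, named or not, gave 4236, 3346 and 3223 probes, since more features were counted. Under the remaining alternatives the counts stayed within 1.5 times, from 1441 to 2374, from 1262 to 1703 and from 1239 to 1802 genes. Keeping genes with values on both arrays removed no gene. Centring on control genes added −0.25 to each value of the Th1 and Th0 array and 0.02 to each value of the Th17 and Th0 array, and moved the negative share from 67.9% to 86.6% for Th1 against Th0 and from 44.4% to 22.3% for Th17 against Th1. Centring on the median moved the first to 56.5% and the second to 51.1%, and scaling to a common spread moved the second to 54.0%, so the side with more genes turned for Th17 against Th1. Of the list medians, 3 in the outer 2.5% of random lists on either side changed sign, all with control-gene centring: cell cycle genes for Th1 against Th0 (−0.027), and chemokine receptors and homing genes (0.065) and stress and heat shock genes (0.00035) for Th17 against Th1. The constant that this centring subtracts is the cause by construction. In the other 339 comparisons of a list with an alternative, no such median changed sign. For named genes, 29 values moved by more than the probe SD, 28 of them when arrays were scaled to a common spread. The correlation between arrays ranged from 0.526 to 0.538. With 1 array per group the spread between samples is unknown, and the table gives no signal over background beyond the probes with at most 5 units.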

Other observations

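Basophil, mast cell and eosinophil genes lay mostly on the positive side of both arrays. The 14 measured markers whose values had not been seen when they were listed had a median of 1.83 on the Th1 and Th0 array and 1.40 on the Th17 and Th0 array, and their median difference was −0.15, at percentile 6.91 of random lists, with 5 members at least 2-fold negative and 1 positive. Over all 19 measured markers, which include 5 chosen for their high values on the Th1 and Th0 array, the median difference was −1.08, at percentile 0, with 10 negative members and 1 positive member. Among the markers already seen to be high on the Th1 and Th0 array were Fcer1a and Gata2. Fcer1a, part of the IgE receptor, lay at 2.67 (6.38-fold) and at 0.61 on the Th17 and Th0 array. Gata2, a transcription factor of these lineages, lay at 2.62 and 0.90, and Ms4a2, the beta chain of the IgE receptor, which had not been seen, at 2.30 and −0.05. The mast cell proteases Cma1 and Mcpt4 lay at 2.28 and 1.40 on the first array and at 0.97 and −0.13 on the second. By contrast, Kit, the stem cell factor receptor, lay at 2.43 and 2.31, Prg2, an eosinophil granule protein, at 2.07 and 2.70, and Hdc, which makes histamine, at 1.85 and 2.18.

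Setting aside genes with a weaker channel of at most 5 units, a step taken after the data were seen, brought other genes to the ends of the difference between Th17 and Th1. Olfr820 at 6.18 and Dkk2 at 5.02 still led the positive end. However, the ratios of stronger to weaker channel on the Th1 and Th0 array of Olfr820 (40.987), Dkk2 (17.503) and Olfr1290 (32.009) lay near ratios of whole numbers, outside the search's tolerance. These genes may have stayed for that reason alone. Newly at the positive end were Olfr1290 at 4.31, Olfr1462 at 4.16 and Arvcf at 3.55, so olfactory receptor genes stayed there, in part perhaps through that tolerance. Also new were Hopx, a homeodomain gene of effector T cells, at 4.28, Ms4a4c at 4.17, Ms4a4b at 3.82, Esm1 at 3.53 and the interferon-inducible gene Ifi204 at 3.46. The other end was still led by Ccl20 and Il17a, with Olfr181 and Olfr944 among the 10. Newly entered were Vip at −4.12, the macrophage genes Arg1 at −3.91 and Rnase6 at −3.97, the lysozyme gene Lyz1 at −3.84, and Cd302, a lectin receptor, at −3.97. On the Th17 and Th0 array the ratios of stronger to weaker channel of Olfr181 (80.975), Olfr944 (33.996) and Vip (44.008) lay near whole numbers, outside the search's tolerance. These genes may thus rest on a channel of at most 5 units.

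The median over 72 ribosomal protein genes was 0.23 on the Th1 and Th0 array, −0.19 on the Th17 and Th0 array and −0.46 in the difference, and 1 of them was 2-fold apart on the first and 0 on the second. Unnamed probes matched a weaker channel of at most 5 units more often than named ones, 3.85% against 2.67% on the Th1 and Th0 array and 3.30% against 1.79% on the Th17 and Th0 array.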
